A study of Drosophila melanogaster with 53 samples.

How the data were processed

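RNA was taken from muscle of adult *Drosophila melanogaster* kept at 25 °C and 60% humidity, and from whole flies for the Ago1 precipitates, per the labels' protocols. The libraries were made from polyadenylated RNA. STAR, HTSeq and DESeq and the genome build dm6 are named without versions, per the submitters' processing notes. Whether the counting used strand is not given in the sources used here, so reads of a gene and of an overlapping antisense gene cannot be told apart. Reads shared by close copies (AttA and AttB, the cecropin genes, the Hsp70 copies, Jon25Bi and Jon25Bii, the yolk protein genes) may be split between them.

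The deposited tables hold 3 kinds of value. The signal in 3 tables (male ageing, the Atg8a and daw 3' UTR set, the miR-252 and foxo set) is a normalised read count per gene and library, which the authors made with DESeq size factors within each table. Values of different tables were never tested against each other. The authors' comparison tables give a mean normalised count, a log2 fold change with its standard error, and a Wald p-value with its adjusted form for each gene. Whether those deposited log2 values were shrunk is not given in the sources used here. For the axenic flies and the Ago1 precipitates only these comparison tables were used, so no test was fitted to them.

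Each library's normalised values were whole multiples of the value of 1 read. Dividing by that value gave whole reads for 100% of the values in every library, within 0.01, and 2358162 to 4078819 reads per library. By table the totals were 2838395 to 3487569 in male muscle, 2358162 to 4023468 in the Atg8a and daw 3' UTR set and 3294056 to 4078819 in the miR-252 and foxo set. The tables list 10657, 10222 and 10258 genes, no library pair held identical values, and both female tables list no mitochondrial genes. The miR-252 and foxo table names genes by symbol. Of its 10258 entries, 8241 matched a current symbol, 1631 a symbol paired with an identifier in another deposited table and 358 a unique RefSeq synonym, while 28 did not match. The WT columns of that table carry no number that links them to single samples, so they were used as 3 libraries of the WT group.

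The main test was limma (version 3.58.1, R 4.3.3) with a trend on log2 of the normalised value plus a pseudocount of 1. It ran on genes with a mean of at least 10 over the table (8393, 8271 and 8357 genes), with all groups of a table in the fit and no replicate block. Benjamini-Hochberg adjusted p-values under 0.05 were called, with no fold minimum. Fold changes are on this log scale and understate changes of low genes. Where all libraries of a group were at 0, a fold is given as a bound against a floor of 3 reads over that group, which covers counting error only. Mutants of a set share their WT libraries and the ages share the 3 d libraries, so chance values are shared between such comparisons. The design, the gene lists, the rule for naming genes and the other settings to try were fixed before the data were examined, except the lists and sets without 3 d replicate 3.

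In all 25 gene lists were drawn up, 16 of pathways or complexes and 9 of markers for tissues and sex that dissected muscle could carry. Thor and tobi each stand in 2 lists. The lists were tested with camera in limma at a preset correlation between genes of 0.01 and again with an estimated correlation, adjusted over the lists within each comparison. A list needed at least 3 measured genes. Camera compares a list with the other genes of the table. Members were counted from the gene-wise test, adjusted over all genes and adjusted over the list alone. Of 305 list tests in 13 comparisons, 120 passed at the preset correlation and 10 with an estimated one. Markers of testis and accessory gland had fewer than 3 tested genes in every muscle table, and ovary markers had enough only in the miR-252 and foxo set.

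Genes named in the text were the study's own (daw, foxo, Atg8a, mir-252, babo, Actbeta, AGO1), and the 6 largest rises and 6 largest falls per comparison. The latter had to pass the threshold with groups whose ranges did not overlap, a mean of at least 50 in the higher group and a symbol other than a CG or CR number. For each list with at least 3 called members, up to 4 members with the smallest adjusted p were added. For the interaction and the precipitates 8 genes each way were taken, with a mean of at least 100 for the precipitates. Non-overlap was not applied to the interaction, which has 4 groups, nor to the deposited comparison tables. List members named from the Ago1 and axenic tables were chosen after their values were seen.

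Alternatives were a pseudocount of 8, no filter on low values, rescaling to a common upper quartile, edgeR (4.0.16) and DESeq2 (1.42.0) on the whole reads, only the groups compared in the fit, the replicate number as a block, and leaving out each library in turn. On simulated reads with 200 changed genes, drawn for the 45 d against 3 d comparison (8388 genes), limma recovered 4.48%, 42.4% and 92.4% of genes changed 1.5-, 2- and 4-fold, and 2.13% of its calls were false. For miR-252 foxo against WT (8361 genes) these were 25.8%, 77.6% and 97%, with 5% false, and for daw 3' UTR foxo against WT (8259 genes) 27.3%, 78.1% and 95.3%, with 3.73% false. Figures and tables were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9. Seed matches of miR-252 in transcripts were not analysed here.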

Results

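Messenger RNA was measured in *Drosophila melanogaster* by sequencing of polyadenylated RNA, in 53 samples that fall into 19 groups. Muscle of male control flies was sampled at 3, 15, 30 and 45 d of adult age, with 3 libraries per age. Muscle of females at 3 d was sampled in 2 sets of mutants, each with its own wild-type (WT) libraries. The first set held WT, homozygous Atg8a mutants, mutants of the daw 3' UTR and daw 3' UTR foxo double mutants. The other set held WT, miR-252 mutants, foxo mutants, miR-252 foxo double mutants and miR-252 foxo double mutants that also carried 1 mutant copy of daw. All of these had 3 libraries per group. For axenic foxo and WT females (3 libraries each) and for the HA-Ago1 immunoprecipitates of whole flies at 3 and 30 d (2 input and 2 precipitated libraries per age), only the authors' deposited tables of comparisons were used. The 39 libraries with values of their own held 2358162 to 4078819 reads on listed genes. The labels do not say that libraries of a group came from separate animals, so the p-values measure the spread between these samples, which may be technical.

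The genes named by the study lie at these places in the BDGP6 annotation. The activin-like ligand gene daw (FBgn0031461) spans 2L 2805261 to 2812376, and foxo (FBgn0038197), which encodes the transcription factor restrained by insulin signalling, spans 3R 14056945 to 14087978. Atg8a (FBgn0052672), the ubiquitin-like protein coupled to autophagosome membranes, lies on X from 10764878 to 10768338. The microRNA gene mir-252 (FBgn0262323) occupies 3R 13464219 to 13464311, and its short product was not measured in the libraries used here.

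The male series asks how the muscle transcriptome changes with age. Atg8a fell at each later age, from 3459 ± 254 normalised reads at 3 d to 1735 ± 89.5 at 15 d, 1558 ± 51.8 at 30 d and 1401 ± 29.5 at 45 d (SD, n = 3, log2 -1.30 ± 0.12 SE at 45 d, limma adjusted p = 1.81e-05). Among the genes that fell furthest, Scp1, a sarcoplasmic calcium-binding protein, went from 22680 ± 2310 reads at 3 d to 845.5 ± 59.1 at 30 d and 575.8 ± 64 at 45 d (log2 -5.30 ± 0.15, adjusted p = 2.31e-09). The troponin C gene TpnC4 went from 4503 ± 873 to 88.28 ± 26.5 at 45 d (log2 -5.69 ± 0.26, adjusted p = 8.65e-08). The neuropeptide-like gene Nplp3 had fallen by 15 d, from 4571 ± 2130 to 137.7 ± 20.9 reads, and the larval serum protein gene Lsp1gamma by -5.94 on the log2 scale. The named genes with the largest rises at 45 d included several antimicrobial peptide genes, which encode secreted products of the humoral immune response. AttC went from 83.72 ± 68.1 to 1673 ± 914 reads (24.5-fold, log2 4.61 ± 0.74, adjusted p = 0.00104) and DptA from 25.74 ± 17.4 to 531.3 ± 298 (adjusted p = 0.000739). AttB rose by 4.88 ± 1.18 on the log2 scale (adjusted p = 0.013). AttA and AttB are near-identical copies whose reads may have been split by the counting. For daw, the mean was 246.7 ± 82.9 at 3 d and 254.6 ± 21.8 at 45 d (adjusted p = 0.827), and for foxo it was 581.4 ± 244 and 475.5 ± 30.8 (log2 -0.19, adjusted p = 0.664). The 3 d foxo value rested on replicate 3, at 320 reads against 803.1 and 621.1 in the others. Without it foxo fell at 45 d (log2 -0.57, adjusted p = 0.000125), as did babo, the type I receptor gene of activin ligands (-0.50, adjusted p = 0.000303). There daw did not pass (-0.11, adjusted p = 0.64).

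**Figure D1:**
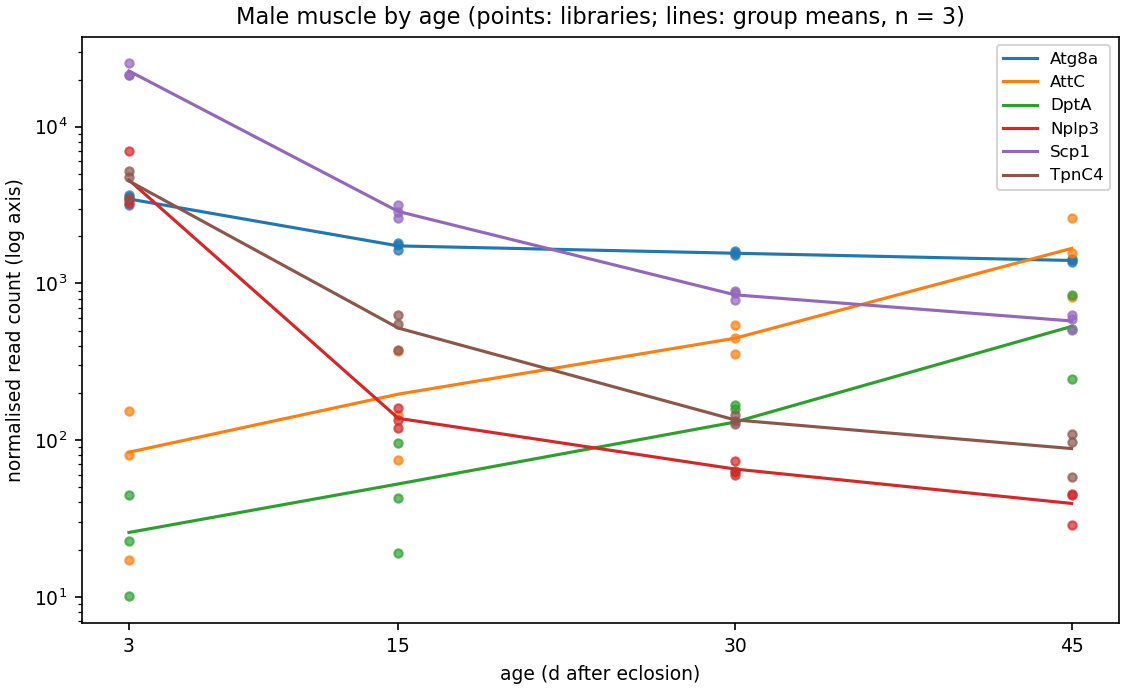
Normalised read counts (log axis) of 6 genes in male muscle against age in days, with a point per library and a line through the mean of the 3 libraries of each age. Scp1, TpnC4, Nplp3 and Atg8a are lower at 45 d than at 3 d, and AttC and DptA are higher.

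Several gene lists moved as groups with age. Of 70 measured nuclear genes of oxidative phosphorylation, 64 fell at 15 d, 63 at 30 d and 65 at 45 d (68, 64 and 69 adjusted over the list alone). Their median log2 changes were -1.87, -1.91 and -2.17, with camera adjusted p = 8.06e-61, 1.02e-48 and 2e-50. None of these calls held with an estimated correlation (adjusted p = 0.076, 0.125 and 0.0968 with an estimated correlation). ATPsynC, a subunit of the ATP synthase membrane ring, fell to 0.104 of its 3 d level at 45 d (log2 -3.27 ± 0.12). Among 14 glycolytic genes 12 fell at each later age (also 12 adjusted over the list alone, with 1 higher at 45 d), with medians of -1.62, -1.88 and -2.08. With all libraries the glycolysis calls held, with adjusted p = 0.00992, 0.0136 and 0.0187 with an estimated correlation, and the glycolytic dehydrogenase gene Gapdh1 fell at 45 d (log2 -4.19 ± 0.12). Sarcomere genes, 32 measured, fell in 20, 21 and 24 cases (23, 25 and 25 adjusted over the list alone), with 1 rise at 45 d (2 adjusted over the list alone), at medians of -1.55, -1.66 and -1.82. Camera gave the sarcomere list adjusted p = 0.0419, 0.0421 and 0.0794 with an estimated correlation, so that the call at 45 d (2.15e-18 at the preset correlation) was lost there. Without 3 d replicate 3, which stood apart from the other 3 d libraries, the medians were -1.52, -1.78 and -2.12 for glycolysis (12 of 14 lower and 2 higher at each age). For the sarcomere list they were -1.91, -2.14 and -2.31 (30, 30 and 29 of 32 lower and 1 higher at each age). Both lists passed there at the preset correlation (camera adjusted p = 1.22e-13, 1.35e-11 and 2.18e-10, and 5.85e-30, 7.67e-24 and 9.4e-20). Neither held with the estimated one, each list being at adjusted p = 0.119, 0.117 and 0.152 with an estimated correlation.

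Several lists of immune and protein-quality genes passed as higher at 30 or 45 d. Of 20 antimicrobial peptide genes, 5 rose at 30 d and 12 rose and 1 fell at 45 d (7 higher and 1 lower, then 13 higher and 1 lower, adjusted over the list alone). The list median at 45 d was 2.85 (camera adjusted p = 1.11e-05, and adjusted p = 0.546 with an estimated correlation). Among 31 components of the Imd and Toll pathways 9 rose at 45 d (9 adjusted over the list alone), with a median of 0.30 (camera adjusted p = 0.00107, and adjusted p = 0.0968 with an estimated correlation). They included Rel, the NF-kappaB factor of the Imd pathway (log2 1.19 ± 0.19, adjusted p = 0.000914), and its feedback inhibitor pirk (2.64). Proteasome subunit genes rose in 9 of 31 cases at 45 d (9 adjusted over the list alone), among them Rpn2 (0.99 ± 0.14) and Rpn3 (0.89). Their median was 0.37 (camera adjusted p = 5.16e-05, and adjusted p = 0.701 with an estimated correlation). Of 23 heat shock and chaperone genes 7 rose and 1 fell at 30 d (8 and 1 adjusted over the list alone), with a median of 0.65 (camera adjusted p = 0.0013, and adjusted p = 0.616 with an estimated correlation). At 45 d 5 of them rose and 3 fell (median -1.02, camera adjusted p = 0.725). Without 3 d replicate 3, proteasome genes rose in 10, 19 and 29 of 31 cases at the 3 ages, over all genes tested (median 0.60 at 45 d). Imd and Toll components then rose in 12, 14 and 16 of 31 and fell in 2, 4 and 2, and antimicrobial peptide genes rose in 15 of 20 at 30 d and 17 at 45 d, with 1 fall each. The proteasome and Imd and Toll lists passed there at every age (camera adjusted p = 0.00124 and 0.0231 at 15 d, and adjusted p = 0.539 and 0.351 with an estimated correlation). At 45 d all 3 lists were at adjusted p = 0.152 with an estimated correlation. The time at which these genes rise was not tested. Ilp6, an insulin-like peptide, rose at 45 d (log2 1.30 ± 0.20, adjusted p = 0.000683), as did the coactivator gene srl (1.55), while the translation inhibitor gene Thor fell (-0.70).

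Markers of other tissues moved with the same groups. Cuticle and tracheal genes fell in 7, 9 and 9 of 21 cases (10, 9 and 10 adjusted over the list alone, with 1 higher at 45 d), with a median of -0.99 at 45 d (camera adjusted p = 1.04e-05). This list held at all 3 ages with all libraries (adjusted p = 0.0118, 0.0174 and 0.0262 with an estimated correlation) but not without 3 d replicate 3 (adjusted p = 0.134, 0.117 and 0.152 with an estimated correlation). Its medians without that library were -0.95, -1.10 and -1.17, against -0.93, -0.92 and -0.99 with it. There 13, 12 and 13 of 21 fell (camera adjusted p = 4.74e-05, 0.000153 and 0.000646), and 2 rose at 30 d and 1 at 45 d. Of 11 fat body markers 4 rose at 45 d (4 adjusted over the list alone, median 0.49, camera adjusted p = 0.0177, and adjusted p = 0.0968 with an estimated correlation), among them the lipid droplet gene Lsd-1 (1.38 ± 0.16). At 30 d 4 of them rose (6 adjusted over the list alone, median 0.69), and the list held (adjusted p = 0.0421 with an estimated correlation). Without 3 d replicate 3 it did not hold there (adjusted p = 0.117 with an estimated correlation), with a median of 0.81 and 9 of 11 higher (camera adjusted p = 1e-05). Gut markers rose in 2 and fell in 4 of 14 cases at 45 d (2 and 5 adjusted over the list alone, median -0.43, camera adjusted p = 0.0274, and adjusted p = 0.707 with an estimated correlation). The eye genes ninaE, Arr1 and Arr2 fell (-4.56, -4.35 and -4.30), although the list of 4 did not pass (adjusted p = 0.058). The camera adjusted p at 45 d was above the threshold for the lists of autophagy (0.132), circadian clock (0.493), insulin and FoxO signalling (0.322), JNK and JAK-STAT response (0.634) and lysosome (0.663). It was above it also for oxidative stress (0.211), TGF-beta and activin signalling (0.725), microRNA pathway (0.211), hemocyte (0.725), neuron (0.15) and sex (0.559) markers, and cytosolic ribosomal proteins (0.559). Without 3 d replicate 3, the ribosomal protein list passed as higher at 45 d (adjusted p = 1.63e-19, and adjusted p = 0.167 with an estimated correlation). So did the oxidative stress list (0.000359, and adjusted p = 0.152 with an estimated correlation). There the neuron (2.8e-07), autophagy (0.0257) and sex (0.0282) lists passed as lower, while the gut list no longer passed (0.624). These 3 calls were lost at adjusted p = 0.152 with an estimated correlation.

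In limma's test 669 of 8393 genes passed at 15 d (197 higher, 472 lower), 1132 at 30 d (453 higher, 679 lower) and 1586 at 45 d (706 higher, 880 lower). One 3 d library stood apart from the rest. Replicate 3 correlated with the other 3 d libraries at 0.848 and 0.845, against 0.979 between those, and mitochondrial transcripts took 34.39% of its reads, against 26.44% and 24.87% in the other 3 d libraries and 5.514% to 13.41% at later ages. Without it the counts were 2589 (1196 higher, 1393 lower), 3530 (1723 and 1807) and 4090 (1987 and 2103), a nearly even split. Without M_15d replicates 1, 2 or 3 the 15 d count was 373, 411 or 428. Without M_30d replicates 1, 2 or 3 the 30 d count was 700, 706 or 685. The 45 d count was 1007 without M_45d replicate 1 and 1053 without replicate 3. With only the 2 ages compared in the fit, 160 (7 higher, 153 lower), 338 (62 and 276) and 511 genes (126 and 385) passed.

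In the Atg8a mutant, which tests loss of a central autophagy gene, Atg8a stood at 45.38, 42.99 and 60.4 normalised reads, against 3569, 3445 and 2421 in WT (log2 -5.95 ± 0.15, limma adjusted p = 2.11e-12). The daw mean was 178.8 ± 55.9 against 282.4 ± 48.3 (SD, n = 3, log2 -0.68 ± 0.19, adjusted p = 0.036), a call lost in 4 of the 6 fits without 1 library. The tryptophan oxygenase gene v went from 110 to 2.201 reads (log2 -5.24 ± 0.30, adjusted p = 9.88e-08), a variant linked to Atg8a not being excluded. The clock gene tim fell from 551.7 ± 155 to 159.6 ± 40 (log2 -1.77 ± 0.25, adjusted p = 0.000603). The glycine methyltransferase gene Gnmt rose (log2 4.49 ± 0.80), as did the dehydrogenase gene Antdh (3.46 ± 0.34, adjusted p = 4.56e-05). Among antimicrobial peptide genes, Def went from 12.13 ± 4.7 to 123.8 ± 58.6 reads (adjusted p = 0.00162), and CecB, at 0 reads in WT, was at least 10.2-fold higher against a floor of 3 reads.

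Of 81 cytosolic ribosomal protein genes 46 rose (70 higher and 1 lower adjusted over the list alone), such as RpL22 (0.49 ± 0.08) and RpS9 (0.51), with a median of 0.29 (camera adjusted p = 4e-27, and adjusted p = 0.664 with an estimated correlation). Antimicrobial peptide genes rose in 7 and fell in 1 of 26 cases (16 and 2 adjusted over the list alone). Their median of 1.69 is the same with CecB at its bound (camera adjusted p = 7.14e-06, and adjusted p = 0.664 with an estimated correlation). Proteasome genes rose in 4 of 31 cases (4 adjusted over the list alone, median 0.26, adjusted p = 7.72e-06), and 4 of 14 glycolytic genes fell (4 adjusted over the list alone, median -0.16, adjusted p = 0.00103), among them Gpdh1 (-0.88 ± 0.11). Both lists were lost at adjusted p = 0.664 with an estimated correlation. Small heat shock genes rose, namely l(2)efl (1.07), Hsp26 (1.91) and Hsp23 (2.06), in a list of 16 with 5 rises (6 adjusted over the list alone, median 0.11, adjusted p = 0.048, and adjusted p = 0.664 with an estimated correlation). Lysosomal genes (median 0.17, 3 of 33 higher and 1 lower, 6 and 1 adjusted over the list alone) and sarcomere genes (median 0.16, 9 of 33 higher and 3 lower, 14 and 5 adjusted over the list alone) passed at 0.00869 and 0.0475. They were lost at adjusted p = 0.664 and 0.733 with an estimated correlation. Cuticle markers also passed, with 7 of 24 higher and 1 lower (10 and 5 adjusted over the list alone, median 0.45, adjusted p = 0.0119), and oxidative phosphorylation genes passed at a median of -0.06 (4 of 70 lower, 4 adjusted over the list alone, adjusted p = 0.0475). Those calls were lost at adjusted p = 0.664 and 0.733 with an estimated correlation. Among 23 autophagy genes the median (0.21) and the mean (-0.10) differed in sign, the mean carrying Atg8a itself (camera adjusted p = 0.191). Hemocyte markers rose in 3 and fell in 3 of 14 cases (4 and 4 adjusted over the list alone), and the list did not pass (median -0.24, camera adjusted p = 0.261). The prophenoloxidase genes PPO1 and PPO2 (-1.40 and -1.08) and the peroxidasin gene Pxn (-0.47) fell, while NimB5 (0.87) and the collagen IV genes vkg (0.45) and Col4a1 (0.37) rose.

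The test called 818 of 8271 genes in the Atg8a mutant, 427 higher and 391 lower. The count was 443 without Atg8a replicate 1, 511 without Atg8a replicate 2 and 537 with only the 2 groups in the fit.

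**Figure D2:**
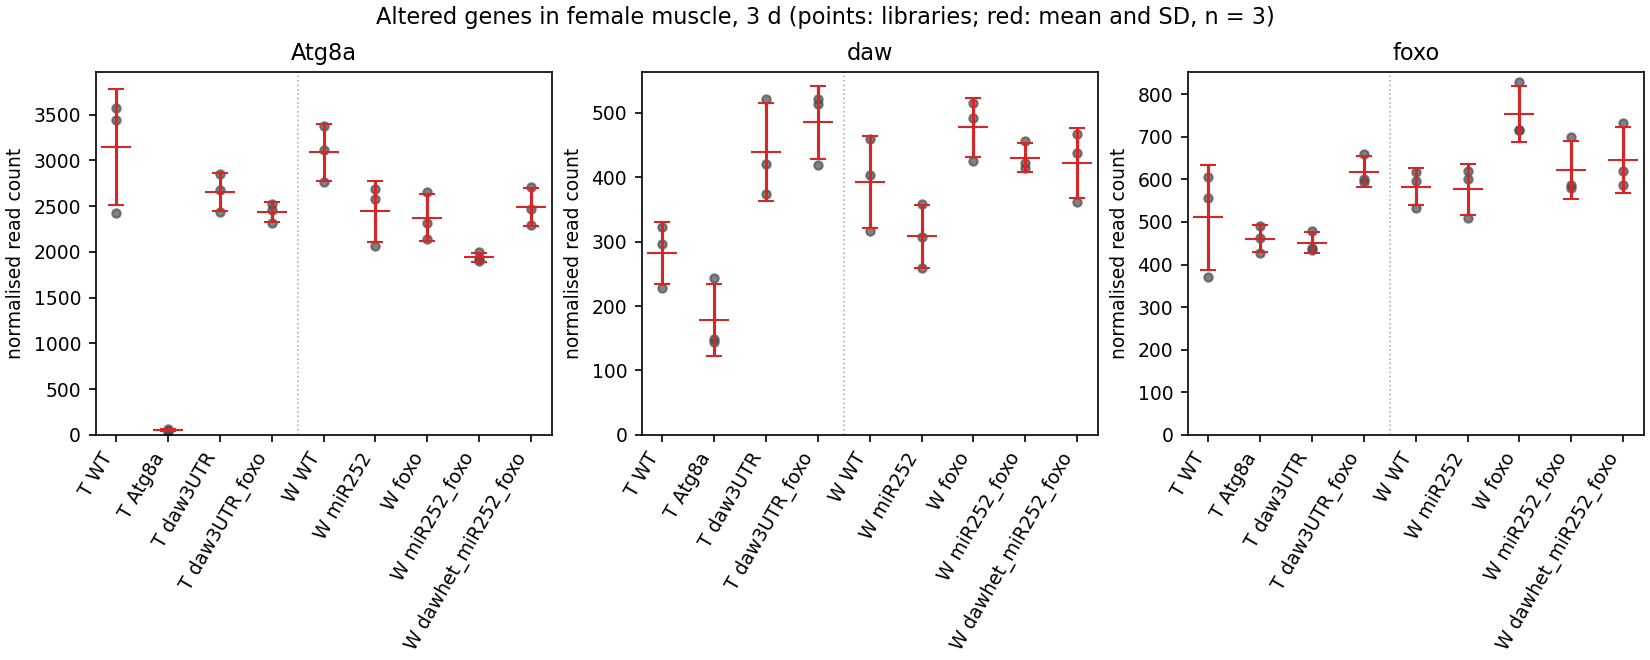
Normalised read counts of Atg8a, daw and foxo in each library of female muscle at 3 d (points), with the mean and SD of 3 libraries in red, the 2 mutant sets being separated by a dotted line. Atg8a is near 50 reads in the Atg8a mutant, and foxo transcript is present in all groups with a foxo mutation.

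The daw 3' UTR mutant tests the regulatory end of the daw transcript. Its daw counts were 421.2, 374.1 and 522.2 against 296.2, 322.2 and 228.6 in WT, higher in 3 of 3 libraries, but the difference did not pass (log2 0.64 ± 0.19, limma adjusted p = 0.103). The digestive amylase gene Amy-d fell from 1811 ± 749 to 89.72 ± 13.2 reads (SD, n = 3, log2 -4.22 ± 0.28, adjusted p = 5.65e-07), phr, a DNA photolyase gene, fell by -3.97 on the log2 scale, and sordd2 went from 50.99 to 0.3033 reads. The alcohol dehydrogenase gene Adh rose from 32.2 ± 3.93 to 185.1 ± 34 reads (log2 2.48 ± 0.17, adjusted p = 5.65e-07) and the cytochrome P450 gene Cyp4e3 from 15.91 to 429.5 ± 315 (4.73 ± 0.53). Gut markers fell in 5 of 14 cases (9 adjusted over the list alone), among them the lysozyme genes LysD (-1.63) and LysP (-0.65), at a median of -0.66 (camera adjusted p = 4.89e-10, and adjusted p = 0.797 with an estimated correlation). Few members of other lists passed singly. Oxidative phosphorylation genes had a median of -0.18 (2 of 70 lower, 3 adjusted over the list alone, camera adjusted p = 7.33e-14), glycolytic genes -0.28 (2 of 14 lower, 9 adjusted over the list alone, 2.29e-06) and ribosomal protein genes 0.10 (2 of 81 higher, 2 adjusted over the list alone, 2.83e-09). These 3 calls ended at adjusted p = 0.944, 0.91 and 0.944 with an estimated correlation. Antimicrobial peptide genes passed too, with 2 of 26 higher (5 adjusted over the list alone, median 0.66, camera adjusted p = 0.00074, and adjusted p = 0.944 with an estimated correlation). So did sarcomere genes, with 1 of 33 lower (4 adjusted over the list alone, median -0.18, camera adjusted p = 0.000137, and adjusted p = 0.944 with an estimated correlation). In all 258 genes passed, 96 higher and 162 lower. This count was 160, 166 and 151 without daw 3' UTR replicates 1, 2 and 3, and 165 without WT replicate 1.

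With foxo mutated as well, the daw 3' UTR foxo double mutant had 485.2 ± 57 daw reads against 282.4 ± 48.3 in WT (SD, n = 3, log2 0.79 ± 0.19, limma adjusted p = 0.00514). The foxo transcript was present at 618 ± 35.9 against 510.6 ± 124 (adjusted p = 0.114), so that its level does not check the mutation. The activin gene Actbeta fell from 58.33 ± 5.45 to 32.02 ± 3.14 reads (-0.85 ± 0.17, adjusted p = 0.00161). Immune genes were among the largest rises, with the serine protease homologue gene SPH93 going from 31.36 ± 28.4 to 2258 ± 1380 reads (6.86 ± 0.92, adjusted p = 6.34e-05), AttA from 50.06 ± 52.4 to 937.5 ± 580, and the cecropin gene CecB, at 0 reads in WT, to 99.62 ± 81.5, at least 83.9-fold higher against the floor of 3 reads. Falls were led by Amy-d (36.37 against 1811 reads, -5.50 ± 0.28), and Ilp6 went from 112.2 ± 25.3 to 15.98 ± 9.83 (-2.92 ± 0.35, adjusted p = 2.44e-05).

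Of 26 antimicrobial peptide genes 23 rose (25 adjusted over the list alone), with a median of 2.74 that is the same with CecB at its bound (camera adjusted p = 1.56e-11, and adjusted p = 0.325 with an estimated correlation). Of 32 Imd and Toll components 21 rose and 1 fell (21 and 2 adjusted over the list alone, median 0.64, camera adjusted p = 1.03e-06, and adjusted p = 0.325 with an estimated correlation). The recognition protein genes PGRP-SA (3.65 ± 0.27, adjusted p = 2.65e-07) and PGRP-LB (3.41) were among them. Oxidative phosphorylation genes fell in 58 of 70 cases (63 adjusted over the list alone, median -0.48, camera adjusted p = 3.26e-20, and adjusted p = 0.325 with an estimated correlation), with the complex II gene SdhB at -0.97 ± 0.08 and the complex I gene ND-B8 at -2.19 ± 0.12. Proteasome genes rose in 26 of 31 cases (27 adjusted over the list alone, median 0.42, camera adjusted p = 1.14e-07, and adjusted p = 0.325 with an estimated correlation). Glycolytic genes rose in 2 and fell in 10 of 14 cases (2 and 10 adjusted over the list alone, median -0.49, camera adjusted p = 0.000198, and adjusted p = 0.367 with an estimated correlation). Genes of the response to oxidative stress and metals rose in 11 and fell in 2 of 27 cases (13 and 3 adjusted over the list alone), led by MtnD (4.02) and GstE1 (3.38 ± 0.23), with camera adjusted p = 0.00242 and adjusted p = 0.325 with an estimated correlation. In the insulin list, ImpL2, a secreted insulin-binding protein, rose (1.59 ± 0.19, adjusted p = 2.91e-05) and the sestrin gene Sesn fell (-1.14), while the list as a whole did not pass (median 0.06, adjusted p = 0.848). TGF-beta and activin genes rose in 2 and fell in 7 of 21 cases (2 and 7 adjusted over the list alone, median -0.10, adjusted p = 0.239). Hemocyte markers rose beside the immune genes in 13 of 14 cases (13 adjusted over the list alone, median 0.96, camera adjusted p = 8.05e-11, and adjusted p = 0.0663 with an estimated correlation), including the collagen IV genes Col4a1 (1.34 ± 0.11) and vkg (1.26). Neuronal markers fell beside them in 14 of 16 cases (15 adjusted over the list alone, median -0.85, camera adjusted p = 2e-08, and adjusted p = 0.325 with an estimated correlation). Cuticle and tracheal markers rose in 15 and fell in 4 of 24 (17 and 4 adjusted over the list alone, median 0.70, camera adjusted p = 0.000267, and adjusted p = 0.325 with an estimated correlation). Gut markers fell in 7 of 14 (7 adjusted over the list alone, median -0.49, camera adjusted p = 0.000267, and adjusted p = 0.367 with an estimated correlation). Ribosomal protein genes passed at a median of 0.16, with 22 of 81 higher and 1 lower (16 higher adjusted over the list alone, camera adjusted p = 5.44e-05, and adjusted p = 0.648 with an estimated correlation). JNK and JAK-STAT response genes passed at a median of 0.30, with 9 of 23 higher and 3 lower (9 and 4 adjusted over the list alone, camera adjusted p = 0.0319, and adjusted p = 0.462 with an estimated correlation).

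Against WT 2960 of 8271 genes passed in this double mutant, 1381 higher and 1579 lower. Against the daw 3' UTR mutant, from which it differs by label in the added foxo mutation, 2532 passed, 1192 higher and 1340 lower. There foxo was at 618 ± 35.9 against 451 ± 24.8 (SD, n = 3, 0.45 ± 0.14, limma adjusted p = 0.0271, lost in 5 of the 6 fits without 1 library). Cyp4e3 was lower, at 9.523 against 429.5 reads (-5.17 ± 0.53, adjusted p = 1.1e-05). CecB stood at 99.62 against 1.253 reads. Antimicrobial peptide genes rose in 18 of 26 cases (21 adjusted over the list alone, median 1.93, camera adjusted p = 1.09e-09, and adjusted p = 0.422 with an estimated correlation). Hemocyte markers rose in 13 of 14 (median 1.08), the call that held in this comparison (adjusted p = 0.047 with an estimated correlation). Neuronal markers fell in 15 of 16 (median -0.76, camera adjusted p = 3.8e-09, and adjusted p = 0.375 with an estimated correlation). Oxidative phosphorylation genes rose in 1 and fell in 43 of 70 cases (1 and 49 adjusted over the list alone, median -0.34, camera adjusted p = 1.02e-11, and adjusted p = 0.516 with an estimated correlation). Cuticle and tracheal markers rose in 14 and fell in 2 of 24 (15 and 3 adjusted over the list alone, median 0.91, camera adjusted p = 3.58e-06, and adjusted p = 0.375 with an estimated correlation). Imd and Toll components (17 of 32, 20 adjusted over the list alone, camera adjusted p = 1.87e-07) and proteasome genes (14 of 31, 22 adjusted over the list alone, 5.44e-07) rose as well. These were lost at adjusted p = 0.375 and 0.422 with an estimated correlation. Oxidative stress genes passed at 0.00299 (13 of 27 higher, 2 lower), sarcomere genes at 0.0176 (17 of 33 higher, 7 lower) and JNK and JAK-STAT genes at 0.0293 (6 of 23 higher, 1 lower). Adjusted over the list alone these were 13 and 3, 20 and 7, and 6 and 1, and the calls were lost at adjusted p = 0.422, 0.722 and 0.516 with an estimated correlation.

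The miR-252 mutant asks what changes without this microRNA, whose own level these libraries do not give. Its daw counts were 259.5, 306.7 and 358.1 against 317.1, 403.1 and 459.3 in WT (log2 -0.35 ± 0.14, limma adjusted p = 0.231), and Atg8a was at 2442 ± 332 against 3086 ± 312 (SD, n = 3, adjusted p = 0.11). The cell surface gene side-IV rose from 21.32 ± 1.46 to 406.4 ± 14.5 reads (4.19 ± 0.14, adjusted p = 1.63e-13), and the stress-response gene TotC from 105.6 ± 49.6 to 853.3 ± 509 (2.95 ± 0.38, adjusted p = 6.43e-05). Among the falls, ND-B8 went from 358.1 ± 85.3 to 22.76 ± 18.6 reads (-4.16 ± 0.40, adjusted p = 1.45e-06), and sordd2 went from 86.94 ± 2.84 reads to 0, at least 89.1-fold lower against the floor of 3 reads. Both genes fell in the foxo mutant as well, and sordd2 in the daw 3' UTR mutant, so these falls are not particular to the miR-252 mutation. Oxidative phosphorylation genes fell in 39 of 68 cases (62 adjusted over the list alone), such as the cytochrome c gene Cyt-c-p (-0.81 ± 0.12, adjusted p = 0.000168), at a median of -0.47 (camera adjusted p = 3.77e-41, and adjusted p = 0.376 with an estimated correlation). Of 24 JNK and JAK-STAT response genes 5 rose (6 adjusted over the list alone, median 0.20, camera adjusted p = 0.000118, and adjusted p = 0.376 with an estimated correlation), among them TotA (1.83) and Xrp1 (0.42). Proteasome genes fell in 2 of 31 cases (2 adjusted over the list alone, median -0.20, camera adjusted p = 5.67e-06, and adjusted p = 0.84 with an estimated correlation). Hemocyte markers passed at a median of 0.13 with 1 of 14 higher (3 adjusted over the list alone, camera adjusted p = 0.0145, and adjusted p = 0.84 with an estimated correlation). Antimicrobial peptides (1 of 24 higher, 1 lower, median 0.63), sarcomere genes (2 of 33 higher, median 0.08) and glycolytic genes (1 of 14 lower, median -0.12) each passed at 0.0497. Adjusted over the list alone these counts were 2 and 1, 2, and 4, and all 3 calls were lost at adjusted p = 0.84 with an estimated correlation. Gut markers rose in 2 and fell in 6 of 14 cases (2 and 8 adjusted over the list alone, median -0.42 but mean 0.18, camera adjusted p = 0.00337 as lower, and adjusted p = 0.811 with an estimated correlation). The 3 ovary markers measured did not pass (median -1.47, adjusted p = 0.45). The threshold was passed by 367 of 8357 genes, 157 higher and 210 lower, with 232 passing without miR-252 replicate 1 and 229 without the WT library in column 1.

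In the foxo mutant the foxo transcript was at 717, 714.9 and 828.5 reads against 596.1, 533.8 and 617.2 in WT (log2 0.37 ± 0.12, limma adjusted p = 0.0455, lost in 6 of the 6 fits without 1 library). Its level therefore does not check this mutation. Atg8a was at 2371 ± 256 against 3086 ± 312 (SD, n = 3, -0.38 ± 0.12, adjusted p = 0.0348, lost in 4 of the 6). Of genes tied to insulin signalling, Sesn fell to 0.456 of WT (-1.13 ± 0.10, adjusted p = 5e-07), Ilp6 fell (-0.88 ± 0.19, adjusted p = 0.00459) and ImpL2 rose (1.00 ± 0.14, adjusted p = 1e-04). The protease gene Jon25Bii went from 50.52 ± 38.3 to 1004 ± 351 reads (4.49 ± 0.45, adjusted p = 1.42e-06), and its near copy Jon25Bi rose with it (4.29), reads between them being uncertain. ND-B8 fell from 358.1 to 4.062 reads (-6.23 ± 0.40, adjusted p = 7.17e-09), sordd2 to 0 (at least 83.8-fold lower), and the maltase gene Mal-B1 by -2.88 on the log2 scale.

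Oxidative phosphorylation genes fell in 38 of 68 cases in the foxo mutant (53 adjusted over the list alone, median -0.42, camera adjusted p = 5.84e-23, and adjusted p = 0.556 with an estimated correlation). Antimicrobial peptide genes rose in 4 of 24 (6 adjusted over the list alone, median 1.40, camera adjusted p = 7.9e-06, and adjusted p = 0.597 with an estimated correlation). Hemocyte markers rose beside them in 7 of 14 cases (11 adjusted over the list alone, median 0.44, camera adjusted p = 1.19e-07, and adjusted p = 0.456 with an estimated correlation). Fat body markers rose in 5 and fell in 1 of 13 (6 and 1 adjusted over the list alone, median 0.44, camera adjusted p = 7.9e-06, and adjusted p = 0.456 with an estimated correlation), among them the yolk protein genes Yp2 (1.12 ± 0.11), Yp3 (0.94) and Yp1 (0.77), whose sequences are similar. Gut markers rose in 6 and fell in 2 of 14 (8 and 4 adjusted over the list alone, median 0.43, camera adjusted p = 0.0203, and adjusted p = 0.597 with an estimated correlation). Neuronal markers fell in 2 of 16 (3 adjusted over the list alone, median -0.27, camera adjusted p = 0.00357, and adjusted p = 0.597 with an estimated correlation). Imd and Toll components passed as higher (5 of 31 higher and 1 lower, 5 and 1 adjusted over the list alone, camera adjusted p = 0.0146, and adjusted p = 0.556 with an estimated correlation). Glycolytic genes passed as lower (1 of 14 higher and 2 lower, 1 and 5 adjusted over the list alone, camera adjusted p = 0.046, and adjusted p = 0.783 with an estimated correlation). Genes of the insulin and FoxO list rose in 4 and fell in 3 of 25 cases (5 and 3 adjusted over the list alone, median -0.05, adjusted p = 0.768). In this mutant 988 genes passed, 463 higher and 525 lower, and 608 passed without the WT library in column 3.

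Flies labelled as mutant for both miR-252 and foxo had 1939 ± 52.6 Atg8a reads against 3086 ± 312 in WT (SD, n = 3, log2 -0.67 ± 0.12, limma adjusted p = 0.000223). The daw level was 430.4 ± 22.5 against 393.2 ± 71.6 (0.15, adjusted p = 0.5), and foxo transcript was at 622.1 ± 67.5 (0.09, adjusted p = 0.616). Actbeta fell from 50.52 ± 13.8 to 32.2 ± 3.5 (-0.60 ± 0.21, adjusted p = 0.0428, lost in 5 of the 6 fits without 1 library). The larval serum protein gene Lsp1beta went from 62.56 ± 36 to 3274 ± 1520 reads (5.73 ± 0.42, adjusted p = 2.16e-08), CecB from 1.35 ± 1.52 to 99.17 ± 22 (adjusted p = 4.49e-06) and SPH93 from 0.6652 ± 1.15 to 314.6 ± 22.2 (adjusted p = 7.58e-05). ND-B8 fell to 2.868 reads (-6.53 ± 0.40, adjusted p = 4.5e-09), sordd2 to 0 (at least 102-fold lower), and the maltase genes Mal-B1 and Mal-A8 fell (-3.98 and -3.70). In the insulin list ImpL2 rose (1.89 ± 0.14, adjusted p = 2.86e-08) and Sesn fell (-1.13).

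Of 24 antimicrobial peptide genes 23 rose in this double mutant (24 adjusted over the list alone, median 2.84, camera adjusted p = 3.72e-11, and adjusted p = 0.359 with an estimated correlation). Of 31 Imd and Toll components 14 rose and 1 fell (14 and 1 adjusted over the list alone, median 0.39, camera adjusted p = 1.45e-05, and adjusted p = 0.176 with an estimated correlation), among them Rel (1.40 ± 0.15, adjusted p = 1.32e-06), PGRP-SA (3.62 ± 0.35) and the Toll ligand gene spz (1.34). Oxidative phosphorylation genes fell in 66 of 68 cases (67 adjusted over the list alone, median -0.93, camera adjusted p = 4.33e-45, and adjusted p = 0.176 with an estimated correlation), with Cyt-c-p at -1.25 ± 0.12 (adjusted p = 3.38e-07). Sarcomere genes rose in 7 and fell in 5 of 33 cases, and their median (-0.02) and camera's direction (up, adjusted p = 0.85) differed in sign. Glycolytic genes rose in 1 and fell in 10 of 14 cases (1 and 12 adjusted over the list alone, median -0.52, camera adjusted p = 3.53e-05, and adjusted p = 0.395 with an estimated correlation). JNK and JAK-STAT response genes rose in 11 and fell in 1 of 24 cases (median 0.41, camera adjusted p = 0.000172, and adjusted p = 0.176 with an estimated correlation), such as Socs36E (2.12), Gadd45 (2.30) and the tumour necrosis factor gene egr (1.20). The small heat shock genes Hsp27 (3.42 ± 0.43, adjusted p = 1e-05), Hsp26 (2.95) and Hsp23 (2.72) rose, while the chaperone list did not pass as a whole (median 0.30, adjusted p = 0.08). Hemocyte markers rose beside the immune genes in 13 of 14 cases (median 0.75, camera adjusted p = 1.08e-09, and adjusted p = 0.176 with an estimated correlation). Neuronal markers fell in 8 of 16 (9 adjusted over the list alone, median -0.46, camera adjusted p = 0.000127, and adjusted p = 0.395 with an estimated correlation). Fat body markers rose in 7 and fell in 1 of 13 (7 and 1 adjusted over the list alone, median 0.46, camera adjusted p = 0.000535, and adjusted p = 0.359 with an estimated correlation). Proteasome genes rose in 6 of 31 (6 adjusted over the list alone, camera adjusted p = 0.00202, and adjusted p = 0.648 with an estimated correlation). Ribosomal protein genes fell in 6 of 82 (1 adjusted over the list alone, median -0.14, camera adjusted p = 0.000195, and adjusted p = 0.672 with an estimated correlation). Oxidative stress genes rose in 10 and fell in 5 of 28 (11 and 6 adjusted over the list alone, camera adjusted p = 0.0288, and adjusted p = 0.536 with an estimated correlation). In all, 2107 of 8357 genes passed, 1033 higher and 1074 lower.

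**Figure D3:**
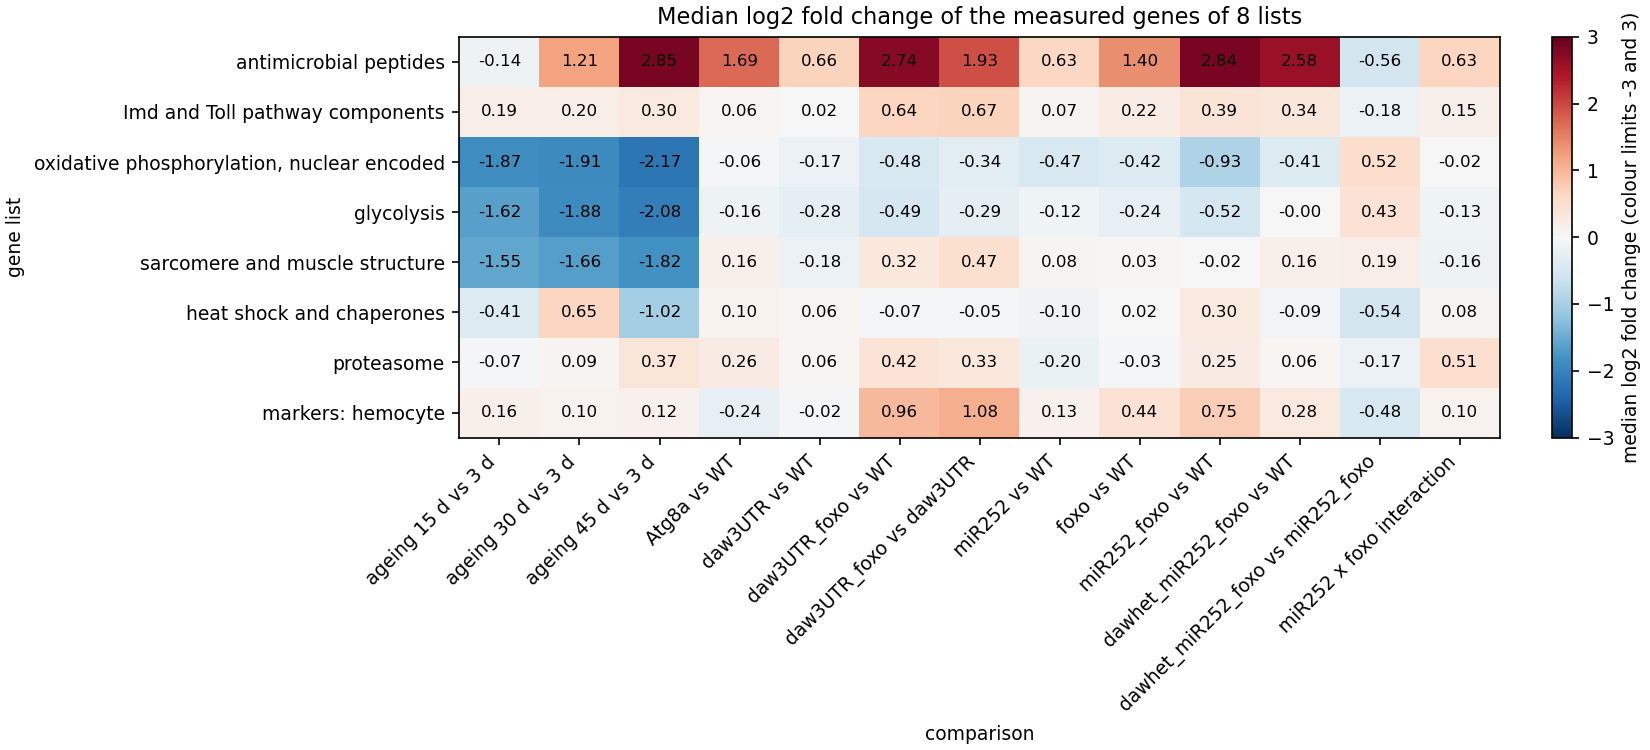
Median log2 fold change of the measured genes of 8 lists (vertical) in each of 13 comparisons (horizontal), as colour between limits of -3 and 3 with the value printed in each cell. Oxidative phosphorylation is lowest in the ageing comparisons (-2.17 at 45 d) and at -0.93 in the miR-252 foxo double mutant, where antimicrobial peptides are at 2.84.

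An interaction tested whether the effect of both mutations differs from the sum of each. Expression in the double mutant lay above the sum for the small heat shock genes Hsp26 (3.75 ± 0.65, limma adjusted p = 0.00246) and Hsp27 (3.25 ± 0.61, adjusted p = 0.00596). It lay below the sum for the proteases Jon25Bii (-6.43 ± 0.64, adjusted p = 4.26e-06) and Jon25Bi (-6.36 ± 0.70), each high in both single mutants. For ND-B8 the value was 3.86 ± 0.57, the gene being near its lowest level in foxo mutants already. Proteasome genes lay above the sum in 4 of 31 cases (16 adjusted over the list alone, median 0.51, camera adjusted p = 7.04e-16, and adjusted p = 0.311 with an estimated correlation). Oxidative phosphorylation genes did not pass (median -0.02, adjusted p = 0.592). In total 175 of 8357 genes passed, 99 above and 76 below the sum, or 113 without miR-252 replicate 1.

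The group with 1 mutant daw copy asks whether less daw changes the double mutant. The daw counts were 437.6, 361.3 and 468, a mean of 422.3 ± 55 against 430.4 ± 22.5 in the double mutant (SD, n = 3, log2 -0.03 ± 0.14, limma adjusted p = 0.931), so that the transcript level does not show the mutant copy. ND-B8 was higher, at 75.51 against 2.868 reads (4.30 ± 0.40, adjusted p = 6.27e-06), as was Pepck2, an enzyme gene of gluconeogenesis, at 467.2 ± 36.4 against 126.5 ± 41.8 (1.93 ± 0.22, adjusted p = 4.2e-05). Hsp27 was lower at 13.34 ± 3.43 against 130.8 ± 46.2 (-3.17 ± 0.43, adjusted p = 0.000444), and so was Arc1, a neuronal capsid-like gene, at 3006 ± 1400 against 13110 ± 3960 (-2.19 ± 0.28, adjusted p = 0.000205). Of 68 oxidative phosphorylation genes 53 rose (66 adjusted over the list alone, median 0.52, camera adjusted p = 6.45e-47, and adjusted p = 0.24 with an estimated correlation), with Cyt-c-p at 0.73 ± 0.12. Glycolytic genes rose in 7 of 14 cases (11 adjusted over the list alone, median 0.43, camera adjusted p = 3.62e-09, and adjusted p = 0.262 with an estimated correlation). Chaperone genes rose in 1 and fell in 8 of 17 (2 and 11 adjusted over the list alone, median -0.54, camera adjusted p = 1.63e-07, and adjusted p = 0.229 with an estimated correlation). Hemocyte markers fell beside them in 6 of 14 (10 adjusted over the list alone, median -0.48, camera adjusted p = 1.07e-08, and adjusted p = 0.24 with an estimated correlation). Sarcomere genes rose in 8 of 33 (11 higher and 3 lower adjusted over the list alone, median 0.19, camera adjusted p = 0.000182, and adjusted p = 0.327 with an estimated correlation). Gut markers rose in 4 and fell in 1 of 14 (8 and 1 adjusted over the list alone, median 0.43, camera adjusted p = 0.000182, and adjusted p = 0.288 with an estimated correlation). Of the 5 eye markers 1 rose (4 adjusted over the list alone, median 2.50, camera adjusted p = 0.00129, and adjusted p = 0.288 with an estimated correlation). Ribosomal protein genes passed as higher (1 of 82 higher, 0 adjusted over the list alone, median 0.10, camera adjusted p = 4.19e-05, and adjusted p = 0.621 with an estimated correlation). Lists passing as lower were proteasome (0 of 31, 0 adjusted over the list alone, median -0.17, 0.000462), oxidative stress (4 of 28 lower and 1 higher, 4 and 1 adjusted over the list alone, 0.00742), Imd and Toll (1 of 31, 1 adjusted over the list alone, 0.0103) and JNK and JAK-STAT genes (4 of 24 lower and 1 higher, 4 and 1 adjusted over the list alone, 0.0162). These 4 were lost at adjusted p = 0.621, 0.46, 0.288 and 0.342 with an estimated correlation. Antimicrobial peptide genes had a median of -0.56 and did not pass (adjusted p = 0.0988). The 425 genes that passed split into 233 higher and 192 lower, or 320 and 153 after rescaling to a common upper quartile. Only 113 passed with the 2 groups alone in the fit, 110 without double mutant replicate 3 and 228 without double mutant replicate 2.

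Of the 2107 genes called in the double mutant, 312 (14.8%) were called in the opposite direction with 1 mutant daw copy and 13 (0.617%) in the same direction. In 50 simulated tables without a daw copy effect, with double mutant libraries shared, a mean of 0.04 genes and at most 1 were opposite. They called 2642 to 2838 genes in the double mutant, against 2107 observed. They thus cannot decide what part of the 312 comes from the shared libraries. The sign was opposite for 82.8% of the 2107, against 60.3% in the simulations. The 312 became 71 without double mutant replicate 3, 168 without double mutant replicate 2 and 203 without replicate 3 of the group with the mutant daw copy. Against WT, this group had 15 of 24 antimicrobial peptide genes higher (21 adjusted over the list alone, median 2.58, camera adjusted p = 1.8e-11, and adjusted p = 0.477 with an estimated correlation). It had 39 of 68 oxidative phosphorylation genes lower (51 adjusted over the list alone, median -0.41, camera adjusted p = 1.81e-18, and adjusted p = 0.477 with an estimated correlation). Hemocyte markers were higher in 4 of 14 cases (7 adjusted over the list alone, median 0.29, camera adjusted p = 0.000621) and neuronal markers lower in 3 of 16 (7 adjusted over the list alone, median -0.34, camera adjusted p = 0.000821). These were lost at adjusted p = 0.477 and 0.497 with an estimated correlation. Fat body markers were higher in 5 and lower in 2 of 13 (7 and 2 adjusted over the list alone, median 0.52), and cuticle markers higher in 6 of 23 (7 higher and 1 lower adjusted over the list alone, median 0.31). Both had camera adjusted p = 0.00562, as had sarcomere genes, with 8 of 33 higher and 2 lower (11 and 2 adjusted over the list alone), and the 3 were lost at adjusted p = 0.477, 0.469 and 0.552 with an estimated correlation. Imd and Toll (9 of 31 higher and 2 lower, 12 and 3 adjusted over the list alone, 0.000293) and JNK and JAK-STAT genes (5 of 24 higher and 1 lower, 7 and 1 adjusted over the list alone, 0.00263) passed as higher. These were lost at adjusted p = 0.4 and 0.469 with an estimated correlation. Its ND-B8 level was 75.51 ± 15.6 (-2.22 ± 0.40), and side-IV was higher (3.83 ± 0.14, adjusted p = 9.12e-13). In that comparison 1326 genes passed, 643 higher and 683 lower, with 852 passing without the WT library in column 3.

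Genes that changed with age in male muscle at 45 d were followed as sets in the female mutants at 3 d, which differ from them in sex. Of 849 measured genes that fell with age, 383 were lower and 62 higher in the daw 3' UTR foxo mutant (median -0.32, camera adjusted p = 1.64e-12), and of 654 that rose with age 239 were higher and 51 lower (median 0.31, adjusted p = 1.62e-08). Both were lost, at adjusted p = 0.151 and 0.141 with an estimated correlation. In the miR-252 foxo mutant 351 of 840 genes that fell with age were lower and 60 higher (median -0.32, adjusted p = 5.68e-15), and 189 of 650 that rose were higher and 39 lower (median 0.26, adjusted p = 2.94e-07). These were lost at adjusted p = 0.141 and 0.151 with an estimated correlation. The foxo mutant moved the same way, with medians of -0.20 (adjusted p = 2.58e-09) and 0.19 (adjusted p = 1.33e-05). Both of its calls were lost at adjusted p = 0.151 with an estimated correlation. For genes falling with age, the daw 3' UTR mutant had a median of -0.13 (adjusted p = 1.72e-10, and adjusted p = 0.179 with an estimated correlation) and the miR-252 mutant -0.08 (adjusted p = 0.00013, and adjusted p = 0.366 with an estimated correlation). Genes rising with age did not pass in either (adjusted p = 0.0732 and 0.132). In the Atg8a mutant the medians were 0.03 and -0.03 (adjusted p = 0.0794 and 0.0817). With 1 mutant daw copy beside miR-252 and foxo, the rising set had a median of 0.08 (adjusted p = 0.0196, and adjusted p = 0.432 with an estimated correlation) and the falling set -0.09 (adjusted p = 0.0423, and adjusted p = 0.543 with an estimated correlation). When 3 d replicate 3 was left out in forming the sets, the adjusted p became 0.0369 and 0.0151 for Atg8a, 0.0138 for the daw 3' UTR rising set, 0.241 for the miR-252 falling set and 0.0575 for the rising set with 1 mutant daw copy.

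The daw 3' UTR foxo and miR-252 foxo mutants, compared across tables that share no library, had log2 changes correlated across 8004 genes at r = 0.673 (Spearman's rho 0.612). Genes are not independent replicates, and no p-value was computed. Both mutants raised 604 genes, against 163 for independent lists, and lowered 665, against 203, while 43 went in opposite directions. Both carry a foxo mutation and were set against WT. The overlap therefore does not show that the daw 3' UTR and miR-252 mutations act alike.

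The foxo mutation was also compared with WT in axenic flies, which are kept free of microbes. In the authors' deposited table the foxo transcript had a log2 change of 0.60 ± 0.16 (adjusted p = 0.00629). By the authors' deposited table Jon25Bi rose (3.71 ± 0.21), ImpL2 rose (1.42 ± 0.20, adjusted p = 7.95e-10), and Ilp6 (-1.26) and Sesn (-0.82) fell. Among named genes, the largest fall in the authors' deposited table was in Cyp4p2 (-5.003 ± 0.30, adjusted p = 3.93e-60), beside the tyrosine breakdown genes Hpd (-2.08) and hgo (-2.07). The authors' deposited table called 18 of 70 oxidative phosphorylation genes lower (median -0.37) and 2 of 27 antimicrobial peptide genes higher (median 0.07). Also higher in the authors' deposited table were 5 of 16 hemocyte and 4 of 14 fat body markers. In all it called 586 of 9371 genes (282 higher, 304 lower), and the authors' deposited table for foxo under conventional culture called 1011. Both of the authors' deposited tables called 349 genes, 347 of them (99.4%) with the same sign, 159 higher and 188 lower, against 13.7 and 18 for independent lists. The difference between axenic and conventional flies was not tested.

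Precipitates of HA-tagged Ago1, the Argonaute protein that carries microRNAs, were compared with input RNA of whole flies. In the authors' deposited tables daw was enriched at 3 d (log2 3.12 ± 0.23, adjusted p = 6.47e-41) and at 30 d (3.87 ± 0.33, adjusted p = 4.55e-29), the 19th of 1155 enriched genes with a mean of at least 100 reads at 3 d and the 10th of 984 at 30 d. Values in the authors' deposited tables for foxo were 1.78 ± 0.20 and 1.55 ± 0.37, for Atg8a 1.22 ± 0.14 and 1.76 ± 0.36, and for AGO1, the gene of the tagged protein, 1.92 ± 0.16 and 2.62 ± 0.31. Among genes with that mean, the most enriched in the authors' deposited tables at 3 d included Cyp18a1 (3.92), which inactivates ecdysone, the glycosyltransferase gene fng (3.52) and the growth factor receptor gene Egfr (3.39), and at 30 d the integrin gene mew (4.09) and the homeotic gene Antp (3.92) stood among the first. By the authors' deposited tables, TGF-beta and activin genes were enriched in 14 of 20 cases at 3 d and 12 of 21 at 30 d (medians 1.23 and 1.62). The authors' deposited tables also had clock genes enriched in 10 and 7 of 11 (1.34 and 1.62) and JNK and JAK-STAT genes in 16 of 24 and 13 of 25. Neuronal markers were enriched in the authors' deposited tables in 12 of 15 cases at both ages (medians 1.32 and 1.94), and fat body markers in 11 of 14 at 3 d and 6 of 13 at 30 d (1.25 and 0.32). Of hemocyte markers 6 and 4 of 14 were enriched in the authors' deposited tables, and of cuticle markers 4 of 22 and 5 of 19. Ribosomal protein genes were depleted in the authors' deposited tables in 79 of 82 and 73 of 81 cases (-1.15 and -1.13), proteasome genes in 24 and 9 of 31, testis and accessory gland genes in 12 of 17 and 5 of 18, and oxidative phosphorylation genes in 57 of 86 and 17 of 88. Counts in the authors' deposited tables were 1936 genes enriched and 891 depleted of 10880 at 3 d, and 1596 and 232 of 11110 at 30 d, with 1231 enriched at both ages against 280 for independent lists. The 2 ages were not tested against each other. There are 2 libraries per group, and no precipitate without the tag was analysed here.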

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

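The count of other splits of the libraries was chosen as a test only after the result was seen. Each value in this part comes from the interaction test of the miR-252 and foxo mutations. Each was singled out because the interaction itself passed the threshold. In limma 175 genes passed. Among 100 splits of the 12 libraries into 4 groups of 3, the real one included, 3 gave at least as many, and the highest other split gave 519. A split that calls several times the real count points to a structure of the samples. The splits mix genotypes that differ from WT by up to 2107 called genes, and such differences widen the spread within a split's groups, so this count does not show whether chance can be excluded.

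Above the sum, on the log2 scale, lay Cyp4p2 (5.09), the receptor gene mthl8 (4.276), ND-B8 (3.864), the heat shock genes Hsp26 (3.752), Hsp27 (3.252) and Hsp68 (2.792), and the stress-response gene TotM (2.549). The value for sordd2 (6.458) follows from the floor, since the gene is at 0 in all miR-252, foxo and double mutant libraries. As mthl8 is at 0 in the miR-252 mutant, its value depends on the pseudocount. A floor may also set that of Cyp4p2. Below the sum lay the gut proteases Jon25Bii (-6.433), Jon25Bi (-6.357) and yip7 (-1.365), as well as smp-30 (-2.265), tun (-1.474), the RNA polymerase I subunit gene Polr1E (-1.44), Lsp1gamma (-1.388) and the maltase gene Mal-B2 (-1.367).

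Lists above the sum were, by their median log2 value, antimicrobial peptides (0.633, camera adjusted p = 0.00874), oxidative stress (0.553, 3.69e-06), proteasome (0.505, 7.04e-16), cuticle and tracheal markers (0.393, 0.00874), Imd and Toll components (0.152, 0.00874) and chaperones (0.0816, 0.000137). They were lost at adjusted p = 0.311, or 0.757 for antimicrobial peptides, with an estimated correlation. Those below were neuronal markers (-0.198, 0.0177), sarcomere genes (-0.158, 0.00874), ribosomal proteins (-0.155, 3.69e-06) and gut markers (-0.147, 0.0112). These were lost at adjusted p = 0.68, 0.609, 0.757 and 0.609 with an estimated correlation.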

How the results depend on the processing

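The gene lists and ageing sets formed without 3 d replicate 3 were tested only after that library's values were seen, and all other alternatives here were planned. Counts of called genes stayed within 1.5 times with a pseudocount of 8, no filter, upper-quartile rescaling, edgeR and DESeq2 (for 45 d against 3 d 1622 with edgeR and 1850 with DESeq2 beside 1586, for miR-252 foxo 2160 and 1970 beside 2107). With only the groups compared in the fit they fell to 160, 338 and 511 for the 3 ages, 537 for Atg8a and 113 for 1 mutant daw copy against the double mutant. They rose to 1308 for foxo, 2210 for miR-252 foxo, 2573 for daw 3' UTR foxo against the daw 3' UTR mutant and 237 for the interaction. Why the fit moved them in both directions was not tested. Leaving out each library in turn gave 373 to 2589 at 15 d, 685 to 3530 at 30 d and 1007 to 4090 at 45 d, each highest without 3 d replicate 3. The 4090 genes kept 1581 of the 1586. Further ranges were 443 to 664 for Atg8a, 151 to 305 for the daw 3' UTR, 2314 to 3039 for daw 3' UTR foxo (1817 to 2607 against the daw 3' UTR mutant), 229 to 329 for miR-252, 608 to 834 for foxo, 1504 to 1921 for miR-252 foxo, 852 to 1351 for 1 mutant daw copy against WT, 110 to 479 for it against the double mutant, and 113 to 176 for the interaction. Each of these leaves out a library, and otherwise the cause was not tested. The 312 genes that turned with the daw copy ranged from 71 to 377 (71 without double mutant replicate 3, 168 without replicate 2, 203 without replicate 3 of the daw group), and 527 turned when adjusted over the genes called in the double mutant alone. A 2-fold minimum lowered the Ago1 count at 3 d from 2827 to 1612.

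For gene lists, 120 of 305 tests passed at the preset correlation and 10 with the estimated one, which allows by construction for genes that vary together. Of those 10, the 9 in the ageing comparisons were lost without 3 d replicate 3 (adjusted p = 0.117 to 0.152 with an estimated correlation), while all 9 still passed at the preset one. Their medians were about as large or larger without it, such as -1.91 against -1.55 for sarcomere at 15 d, 0.805 against 0.69 for fat body at 30 d and -1.52 against -1.62 for glycolysis at 15 d. With all libraries and the estimated correlation, the ageing sets lost their calls for daw 3' UTR (0.179, falling), daw 3' UTR foxo (0.141 rising, 0.151 falling), miR-252 (0.366, falling), foxo (0.151 each), miR-252 foxo (0.151 rising, 0.141 falling) and 1 mutant daw copy (0.432 rising, 0.543 falling). Sets taken at 30 d gave 0.401 and 0.0914 for the latter. Without 3 d replicate 3 the sets gave 0.0369 (rising) and 0.0151 (falling) for Atg8a, 0.0138 (rising) for daw 3' UTR, 0.241 (falling) for miR-252 and 0.0575 (rising) for 1 mutant daw copy at the preset correlation, the other calls staying. The cause was not tested. One list result turned: ribosomal proteins at 15 d were lower with all libraries (median -0.255, camera adjusted p = 0.00989) and higher without 3 d replicate 3 (median 0.293, 1.93e-15). Neither call held, at adjusted p = 0.971 and 0.347 with an estimated correlation. Of the named genes (809 values under the main setting), none changed sign while called. Under the alternatives 9546 values stayed on their side of the threshold, 794 lost their call and 18 gained one, 566 of the losses coming from leaving out a replicate and 128 from fitting only the groups compared.

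The replicate numbers were not shown to pair the samples. Same-numbered libraries deviated together with correlations of -0.0969 to 0.175, and no comparison had all 3 above 0.1. With the number as a block, 536, 968 and 1391 genes passed at the 3 ages, 782 for Atg8a, 246 for the daw 3' UTR, 2881 and 2454 for the double mutant against WT and against the daw 3' UTR mutant, and 424 for 1 mutant daw copy against the double mutant. For the interaction and the comparisons with WT in the miR-252 and foxo set, no block was fitted. The numbers of the WT columns there do not match the replicate numbers of the WT samples. The planned test of miR-252 seed sites was not run, since transcript sequences were not used here. In the simulated comparisons, drawn at the depths of these libraries, 4.48% to 27.3% of 1.5-fold changes were recovered, so that genes not called are not shown to be unchanged. No count of called genes was taken at another depth, so how far depth sets this limit was not tested.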

Other observations

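The tests of other splits, of the share of muscle, of 3 d replicate 3, of mitochondrial reads and of strain background were chosen only after the results were seen.

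Genes of sugar-digesting enzymes were among those named in several comparisons. They form no list fixed in advance and were not tested as a group. The maltase gene Mal-B1 rose by 2.83 on the log2 scale in male muscle at 30 d and by 1.77 in Atg8a mutants (a value added after it was seen), and Mal-A4 rose by 2.21 in male muscle at 15 d and 3.34 at 45 d. Mal-B1 fell in female foxo mutants (-2.88), daw 3' UTR foxo mutants (-2.98), miR-252 foxo mutants (-3.98) and those with 1 mutant daw copy (-4.19). The maltase genes Mal-A8 (-2.52 in foxo, -3.70 in miR-252 foxo, -4.07 with the daw copy) and Mal-A6 (-2.29 with the daw copy) fell too. Of the amylases, Amy-d stood at -5.50 in daw 3' UTR foxo and Amy-p at -1.13 in miR-252 foxo. Differences between these mutants were not tested.

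Some early rises with age have not been described above. The receptor gene mthl4 went from 9.947 to 62.02 reads at 15 d (2.49 ± 0.32), and the matrix gene atk rose by 2.25 at 15 d and 2.53 at 30 d. At 30 d the metallothionein gene MtnD (2.94) and the odorant-binding protein gene Obp56a (2.40) were among the largest rises. Of the antioxidant genes, Sod2, the mitochondrial superoxide dismutase, was lower at 45 d (-1.62), while the glutathione transferase genes GstD2 (2.08) and GstD5 (1.80) were higher.

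Nuclear oxidative phosphorylation genes were lower in the miR-252 foxo mutant, and 3 technical explanations were tested. The tables argue against scaling, depth and a smaller share of muscle. The sarcomere median (-0.018) lay 0.909 above that of oxidative phosphorylation (95% bootstrap interval over genes, not libraries, 0.775 to 1.1). The latter median relative to all genes was -0.94 (-0.992 to -0.903) after upper-quartile rescaling, and it was -0.923 (-0.979 to -0.889) on reads thinned to 1 depth. The mutations may lower these genes together, but the list did not pass with an estimated correlation. A strain difference from WT (medians were -0.06 to -0.47 in single mutants) and other changes in cell content (hemocyte markers higher) stay open.

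Oxidative phosphorylation and sarcomere genes were lower with age. Without 3 d replicate 3 the 45 d medians were -1.8 (-2 to -1.65) and -2.31, and with mitochondrial genes left out and libraries scaled to their nuclear reads they were -1.63 (-1.8 to -1.38) and -1.28, which the tables argue against as whole causes. A lower share of muscle would raise markers of all other tissues only if those tissues kept their proportions to each other. Cuticle markers stood at -0.991 (-1.82 to -0.344) while fat body markers stood at 0.494, so the test cannot decide on the share of muscle. The intervals resample the genes of a list, not the libraries. Age itself, maturation of the young adult at 3 d, a lower share of muscle and a change in 1 of the other tissues may each contribute and stay open.

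Genes called in the same direction in mutants of different genes numbered 176 between the single mutants of both female sets, which share no library, with 79 of them higher. In 4 single mutants at once (Atg8a, daw 3' UTR, miR-252, foxo) 5 genes were called alike, named here after their values were seen: CG4653 (4.38, 2.73, 3.77 and 4.64), Arc1 (1.12, 0.834, 1.17 and 1.26), CG43867, Cyp28d1 and Miro. Variants linked to the altered loci cannot be told apart from other sources, since 21 of the 176 lay within 2 Mb of a locus (odds ratio 1.19, interval 0.713 to 1.9, Fisher's exact p = 0.45), an interval that allows both, and calls of single mutants near their own locus had odds ratios of 1.51 for Atg8a (adjusted p = 0.0876), 1.51 for daw (0.269), 1.65 for mir-252 (0.0876) and 1.07 for foxo (0.71). A difference in strain background between the mutants and the WT line may contribute: Atg8a and miR-252, compared with different WT libraries, shared 71 calls in 1 direction against 17.3 for independent lists. Shared effects of the mutations themselves would give such an overlap too and stay open.

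Other splits of the 6 libraries of a comparison were counted. With 3 against 3 there are 10 splits, too few for a share under 0.05, and the real one was the 1 split with as many calls in each of the 12 comparisons. Each other split mixes the groups compared, and their differences widen the spread within it. Low counts there thus do not show whether chance can be excluded. The real counts are given above. The highest of the other splits was 14 for miR-252, 4 for the daw 3' UTR and 2 at 30 d. It was 1 at 45 d and for Atg8a, and 0 in the other comparisons.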
